A study of Homo sapiens with 8 samples.

How the data were processed

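RNA of the human lung cancer cell line H460 was hybridised to 8 Affymetrix arrays, 4 per group. Per the labels, 4 arrays hold TRAIL-sensitive cells and 4 hold cells that became resistant during 6 months of daily TRAIL treatment. Biotin was the label, and RNA came from a Trizol extraction, per the labels' protocols.

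The deposited values are linear intensity signals of 54675 probe sets per array, 62 of them control probe sets. The submitters' processing notes name RMA, with no version given in the sources used here. The deposited intensity values do not have the form of RMA values: they reach down to below 1, and the mean left after trimming 2% of the probe sets at each end is 200 on every one of the 8 arrays. Such a common trimmed mean is how Affymetrix MAS 5-type signals are scaled, so the step that made the values is not settled. Because each array was scaled to one mean, a change in the total amount of RNA per cell cannot be seen in these values, and a few very bright probe sets hardly move the scale. The analysis plan had assumed log2 values and had foreseen log2(signal + 1) if the values proved linear. That transformation was used, with a pseudocount of 1 and no further normalization. A fold change is therefore on the log2(signal + 1) scale, which understates changes of dim genes. Signals of this type carry noise at the low end: 48.1% of values lay under a log2 level of 5, and the median probe set had a mean log2 level of 5.01, a signal of about 31.2. The number of arrays, 4 per group, limits the precision. Arrays have no read depth.

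Gene names came from the platform annotation supplied with the values, which listed 42898 of the probe sets. Of these, 41097 had 1 symbol and 1801 had several and were not used by name. The other 11777 probe sets were not in that annotation and were not named here. Symbols were updated through gene identifiers to the RefSeq gene table of assembly GRCh38.p14, which matched 41043 probe sets. That table was used only for names and for the order of genes. Each gene was represented by the probe set with the highest mean over all 8 arrays, which gave 19775 genes. Genes that share a probe set with another symbol were not analysed here.

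Resistant and sensitive arrays were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) and Benjamini-Hochberg adjustment. A gene was said to have risen or fallen when its adjusted p was below 0.05. The same fit was made for all probe sets without control probe sets. Gene lists were compared with limma's camera at its preset correlation of 0.01, again with Benjamini-Hochberg adjustment, over 37 lists with at least 4 measured members. Camera with a correlation estimated for each list and limma's fry were run beside it. Measures of whole arrays were compared with exact two-sided permutation tests over the 70 assignments of 4 against 4 arrays, for which the smallest possible p is 0.0286. They covered the 3' minus 5' differences of the GAPDH and ACTB control probe sets, which fall or rise with RNA degradation and labelling, the signals of spiked-in control RNAs, the array median and an upper percentile of the probe sets. Replicate numbers in the labels were not used as a block. The labels do not say whether arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

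The gene lists, the tests, most alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 15 largest rises and the 15 largest falls among genes that passed the test, whose groups did not overlap and whose higher group lay above the median probe set, leaving out Y-linked genes and XIST. It also allowed any measured member of the lists of TRAIL ligand and receptors, of death receptor signalling and caspases, and of possible targets of the microRNAs miR-21, miR-30c and miR-100. Of every other list it allowed up to 4 members with the largest changes, or the 2 with the smallest p where none passed.

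The fit was tested on simulated data with the means and spreads of the 19775 genes. It recovered 30 of 67 genes changed 1.5-fold (44.8%), 56 of 67 changed 2-fold (83.6%) and 64 of 66 changed 4-fold (97.0%), with 8 false calls among all other genes. The changed genes were drawn only from those above the median probe set, so these shares do not hold for dimmer genes. Far fewer genes were changed than passed in the data, and genes were drawn independently of each other, so the data may give other shares. A simulated shifted list was called, and 0 lists without a shared member were.

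Alternatives comprised a replicate block, an intensity trend with a robust prior, array weights, a filter on dim probe sets, quantile normalization, median centring, the GAPDH difference as a covariate, a gene-wise unequal-variance test, other ways to choose probe sets, other fold thresholds and leaving out each array in turn. A pseudocount of 16, the joint removal of sensitive array 1 and resistant array 4, and the use of some of these alternatives on single named genes were chosen after seeing the data. Runs of neighbouring genes were sought among 11610 genes above the median probe set, with 1000 shuffles of gene order. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.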

Results

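Gene expression was measured in H460 cells, a human non-small-cell lung carcinoma line, in 4 arrays of TRAIL-sensitive cells and 4 arrays of cells made resistant by 6 months of TRAIL exposure. TRAIL is a ligand of the tumour necrosis factor family that triggers apoptosis through death receptors. The comparison asks which transcripts differ between cells that respond to the ligand and cells that no longer do. The labels give no TRAIL treatment for the sensitive cells and no time since the last exposure of the resistant cells. Resistance therefore cannot be told apart here from the long TRAIL exposure itself or from a different time in culture. The median signal per array lay between 32.6 and 37.4, and 19775 genes were compared. The mean correlation of an array with the other arrays of its group was 0.937 to 0.952, and with arrays of the other group 0.921 to 0.928. Changes are given below as resistant minus sensitive on the log2(signal + 1) scale, with the standard error from limma and n = 4 per group, and adjusted p-values are those of limma with Benjamini-Hochberg adjustment.

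Among the largest rises in resistant cells were those of SPINK6, IL13RA2, MMP1 and BMP2, and among the largest falls those of HPGDS, PPL, FGF13 and SERPINB11. Genes of hypoxia and glycolysis, of the interferon response and of the ATF4 stress response were lower in them, and genes of the cell cycle were higher. In all, 5986 of 19775 genes (30.3%) passed the test, of which 2900 rose and 3086 fell, and 7805 had an unadjusted p below 0.05. A change of at least 2-fold was seen in 1533 genes, 616 higher and 917 lower in resistant cells. Of the 54613 probe sets, 10637 passed, 4984 higher and 5653 lower. The balance of rises and falls depended on the scaling of the arrays. After median centring 3203 genes rose and 2434 fell, 715 and 772 of them at least 2-fold, and 5525 probe sets were higher and 4474 lower. After quantile normalization 3054 genes rose and 2911 fell, 658 and 835 of them at least 2-fold, and 5451 probe sets were higher and 5264 lower. All 4 arrays of one group lay above all 4 of the other for 6712 genes (33.9%), where chance gives 2.86%. Among 586 genes changed at least 2-fold that had another probe set above the median level, 4 had a probe set that passed in the opposite direction: GPATCH2, MACROD1, SLC6A15 and SRSF1, which are named here after their values were seen. With probe sets that carry no suffix for possible cross-hybridisation, 4108 genes passed, 3897 of them among the 5986, and 21 of these in the opposite direction. With the mean of all probe sets of a gene, 4861 passed, 4286 of them among the 5986, and 2 of these in the opposite direction. With a threshold of 1.5-fold in place of 2-fold, 3462 genes passed.

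**Figure D1:**
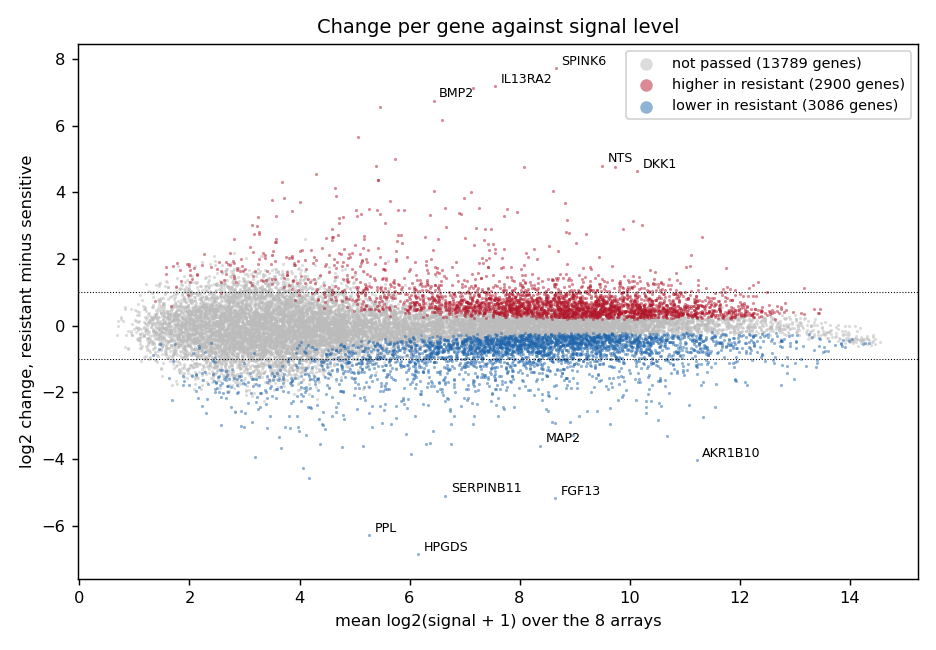
Change per gene (y axis, log2 change, resistant minus sensitive) against mean log2(signal + 1) over the 8 arrays (x axis), 1 point per gene, with dotted lines at 2-fold. Red points are the 2900 genes that rose, blue points the 3086 that fell and grey points the genes that did not pass, and SPINK6 and HPGDS lie at the extremes.

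The largest estimated rise was that of SPINK6, a serine protease inhibitor, from a log2 level of 4.80 ± 0.45 (SD, n = 4) to 12.52 ± 0.16, a change of 7.72 ± 0.23 (adjusted p = 2.78e-06). IL13RA2, a decoy receptor for interleukin-13, rose by 7.18 ± 0.22 and MMP1, the interstitial collagenase, by 7.14 ± 0.53. BMP2, a bone morphogenetic protein, rose by 6.75 ± 0.45, RGS4, a regulator of G-protein signalling, by 6.55 ± 0.50, and POSTN, the matrix protein periostin, by 6.18 ± 0.26. The long non-coding RNA LINC00973 rose by 5.64 ± 0.61, the small GTPase RAC2 by 4.99 ± 0.55 and CEMIP, which takes part in hyaluronan breakdown, by 4.80 ± 0.52. Several genes already well measured in sensitive cells rose as well: NTS, the precursor of neurotensin, from 7.11 ± 0.02 to 11.90 ± 0.06, CA2, a carbonic anhydrase, from 7.36 ± 0.04 to 12.11 ± 0.09, and the Wnt antagonist DKK1 from 7.82 ± 0.09 to 12.45 ± 0.09. ANXA10 rose by 4.74 ± 0.17, ITPKB by 4.54 ± 0.54 and the RNA-binding protein gene IGF2BP1 by 4.38 ± 0.50. All 15 had adjusted p-values of 0.000722 or less. For most of these genes the sensitive level lay below that of the median probe set, 5.01, so the size of the change and its rank rest on noisy low signals there. When probe sets with a suffix for possible cross-hybridisation were left out, the probe set then used for POSTN changed by 1.61 (adjusted p = 0.183).

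HPGDS, a prostaglandin D synthase, had the largest estimated fall, from 9.59 ± 0.06 to 2.73 ± 1.41 (SD, n = 4), a change of -6.86 ± 0.64 (adjusted p = 0.000266). PPL, the desmosome-associated protein periplakin, changed by -6.28 ± 0.17, FGF13 by -5.18 ± 0.08 and the serpin SERPINB11 by -5.09 ± 0.11. AKR1B10, an aldo-keto reductase, lay at 13.24 ± 0.11 in sensitive and at 9.20 ± 0.11 in resistant cells. MAP2, a microtubule-associated protein, fell from 10.17 ± 0.05 to 6.57 ± 0.25. The potassium channel gene KCNJ8 changed by -4.56 ± 0.49, FGG, a fibrinogen chain, by -4.28 ± 0.48, and IFNB1, interferon beta, by -3.94 ± 0.25 from a low level of 5.15 ± 0.32. The connexin gene GJA5 changed by -3.84 ± 0.20, TMEM59L by -3.65 ± 0.23, the antisense RNA FGF13-AS1 by -3.63 ± 0.61, CLTRN by -3.61 ± 0.29, the small GTPase RAB39B by -3.54 ± 0.20 and ZNF831 by -3.53 ± 0.32. All 15 had adjusted p-values of 0.00374 or less. For most of these genes the resistant level lay below that of the median probe set, so the size of the change and its rank rest on noisy low signals there too.

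Transcripts of the TRAIL receptors changed little and in both directions. TNFRSF10B, which encodes a death receptor, fell by 0.36 ± 0.08 (adjusted p = 0.0120), from 11.08 ± 0.04 to 10.72 ± 0.12 (SD). The other death receptor, TNFRSF10A, rose by 0.44 ± 0.10 (adjusted p = 0.0116). The decoy receptors TNFRSF10D and TNFRSF11B, the latter a soluble protein known as osteoprotegerin, rose by 0.59 ± 0.16 (adjusted p = 0.0246) and 0.92 ± 0.08 (adjusted p = 0.000213). The decoy receptor TNFRSF10C changed by 0.02 ± 0.44 and the ligand gene TNFSF10 by -1.16 ± 0.57, neither of which passed (adjusted p = 0.983 and 0.184). Of the 6 members, 3 rose and 1 fell, the same counts as when adjusted over the list alone, and the list was not called (camera adjusted p = 0.483). With the mean of all probe sets of a gene, TNFRSF10A (0.22, adjusted p = 0.130), TNFRSF10B (-0.14, adjusted p = 0.663) and TNFRSF10D (0.89, adjusted p = 0.0544) did not pass and TNFSF10 did (-1.003, adjusted p = 0.0186). TNFRSF10B did not pass after median centring (-0.29, adjusted p = 0.0746), and TNFRSF10D did not pass without resistant array 1, 2 or 3, with changes of 0.44 to 0.67 when leaving out each array and adjusted p-values up to 0.0664.

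**Figure D2:**
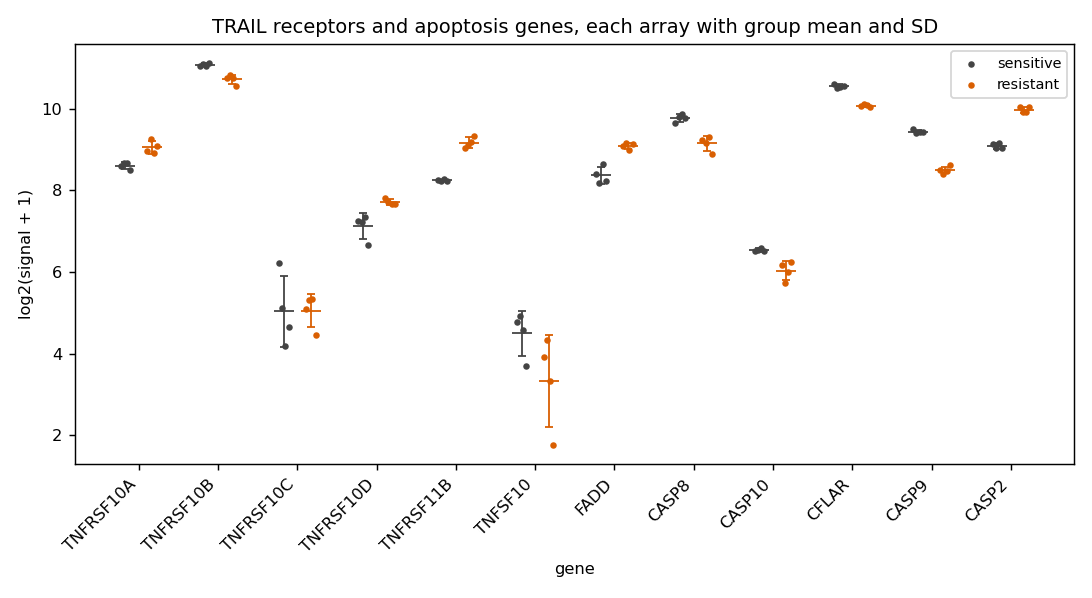
Levels of TRAIL receptor and apoptosis genes (x axis) as log2(signal + 1) (y axis), 1 point per array, with bars for the mean and SD of the 4 sensitive (grey) and 4 resistant (orange) arrays. TNFRSF11B, FADD and CASP2 lie higher in resistant arrays, CASP8 and CASP9 lie lower, and TNFRSF10C and TNFSF10 overlap.

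Apoptosis genes downstream of the receptors moved in both directions. CASP9, the initiator caspase of the mitochondrial pathway, fell by 0.93 ± 0.07 (adjusted p = 0.000107). CASP8, the initiator caspase of death receptors, fell by 0.62 ± 0.11 (adjusted p = 0.00443), CASP10 by 0.50 ± 0.12 (adjusted p = 0.0186) and CFLAR, the gene of the caspase-8 inhibitor FLIP, by 0.48 ± 0.06 (adjusted p = 0.00105). The adaptor gene FADD rose by 0.72 ± 0.12, CASP2 by 0.88 ± 0.07 and the death receptor gene TNFRSF21 by 0.66 ± 0.15. BID (0.38 ± 0.10), CYCS (0.35 ± 0.10) and MLKL (0.26 ± 0.08) passed as well, but not when leaving out any of 4, 5 and 7 of the 8 arrays, with adjusted p-values up to 0.0625, 0.0793 and 0.107. FAS changed by 0.06 ± 0.10 and did not pass (adjusted p = 0.745). Of 20 members measured, 6 rose, 4 fell and 10 did not pass, with 6 and 4 adjusted over the list alone, and the list was not called (camera adjusted p = 0.771). With the mean of all probe sets of a gene, CFLAR turned to 0.11 (adjusted p = 0.559), and CASP8 (-0.63, adjusted p = 0.176) and CASP10 (-0.50, adjusted p = 0.0914) did not pass. On probe sets without a cross-hybridisation suffix CASP9 changed by -0.13 (adjusted p = 0.606) and CASP8 by -0.40 (adjusted p = 0.799). CASP8 lies in a stretch of 355 neighbouring genes along 1 chromosome, of which 199 fell and 38 rose. Of all genes ordered along the chromosomes, 23.9% fell. The stretch came from wide windows chosen after the results were seen. The window of 21 genes centred on CASP8 had a median change of -0.43. In size this lay below 0.666, the 95th percentile of the largest value in shuffles of gene order. Whether CASP10, CFLAR or other genes of this list lie in the stretch was not examined. The falls of CASP8, CASP10 and CFLAR may therefore not be separate results. CASP10 did not pass without sensitive array 3 or resistant array 3, with changes of -0.58 to -0.40 when leaving out each array and adjusted p-values up to 0.0524.

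Members of the BCL2 family showed the same mixture. The pro-apoptotic genes BNIP3L and BNIP3 fell by 1.66 ± 0.07 and 1.02 ± 0.07, and PMAIP1, which encodes NOXA, by 0.40 ± 0.07, while BCL2L11, which encodes BIM, rose by 0.53 ± 0.09. BNIP3 also counts in the list of hypoxia and glycolysis below, so its fall is not a separate result. Of 12 pro-apoptotic members, 2 rose and 3 fell, with 3 and 3 adjusted over the list alone, and the list was not called (camera adjusted p = 0.862). Among 7 genes listed as pro-survival, BAG3, a chaperone partner and not itself a BCL2 family member, rose by 1.06 ± 0.10. MCL1 fell by 0.75 ± 0.11 in this list with 1 rise and 2 falls, the same when adjusted over the list alone (camera adjusted p = 0.999). BCL2L11 did not pass with the mean of all probe sets of a gene (0.37, adjusted p = 0.0930), nor MCL1 on probe sets without a cross-hybridisation suffix (-0.41, adjusted p = 0.154). Of 5 measured genes listed as possible targets of miR-21, miR-30c and miR-100, FOXO3, a transcription factor that promotes apoptosis, fell by 0.91 ± 0.08 (adjusted p = 0.000158) and CASP8 fell as above, the same 2 falls as adjusted over the list alone. PDCD4 changed by -0.66 ± 0.55, TRAF7 by -0.06 ± 0.11 and MTOR by 0.13 ± 0.22, none of which passed, and the list was not called (camera adjusted p = 0.244). FOXO3 did not pass with the mean of all probe sets of a gene (-0.53, adjusted p = 0.0675). MicroRNAs were not analysed here.

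Genes of hypoxia and glycolysis were lower in resistant cells. Camera called 10 of the 37 lists, 3 higher and 7 lower in resistant cells, and 4 of these were also called with an estimated correlation. Of 31 measured genes of hypoxia and glycolysis, 26 fell, 1 rose and 4 did not pass, with 28 falls and 1 rise adjusted over the list alone, and the median change was -1.02 (camera adjusted p = 9.26e-15, and adjusted p = 0.0469 with an estimated correlation). ANKRD37, a target of hypoxia-inducible factors, fell by 3.30 ± 0.08, ANGPTL4, an inhibitor of lipoprotein lipase, by 2.32 ± 0.13, the enolase gene ENO2 by 2.22 ± 0.07 and PFKFB4, a regulator of glycolysis, by 2.06 ± 0.15. Genes of the unfolded protein response and of the transcription factor ATF4 were lower too: 18 of 29 fell and 8 rose, with 19 and 9 adjusted over the list alone (camera adjusted p = 0.00103, and adjusted p = 0.0469 with an estimated correlation). The largest falls were those of PHGDH (-2.94 ± 0.11) and ASNS (-2.36 ± 0.07), enzymes of serine and asparagine synthesis, of CHAC1 (-2.50 ± 0.18), which degrades glutathione, and of the stress-induced transcription factor gene DDIT3 (-1.78 ± 0.09).

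**Figure D3:**
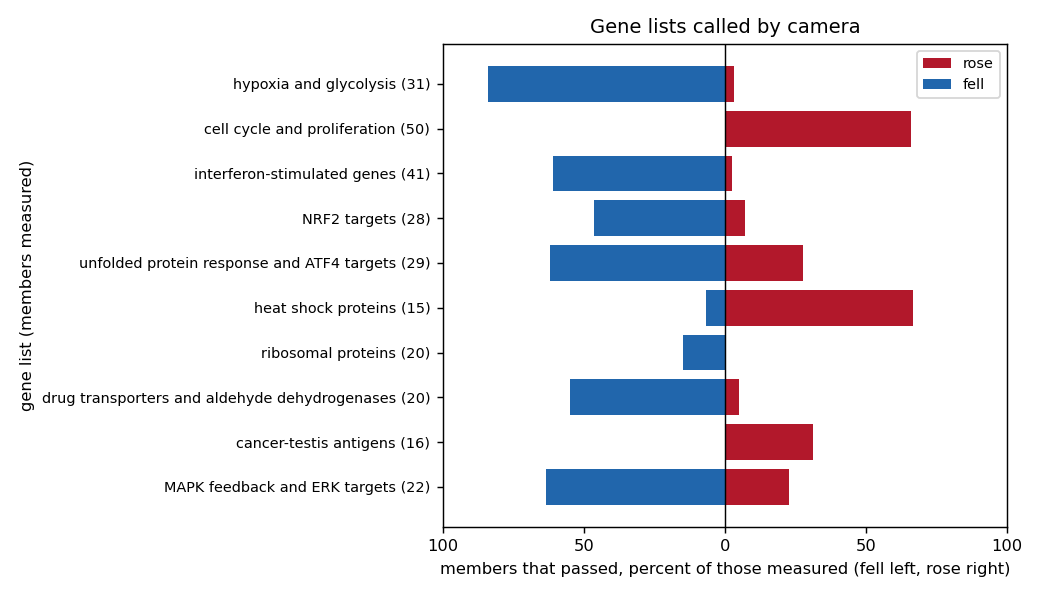
Members that rose (red, right) or fell (blue, left) as a percent of measured members (x axis) in the 10 gene lists called by camera (y axis, measured members in parentheses). In the list of hypoxia and glycolysis 26 of 31 fell, and in that of the cell cycle 33 of 50 rose and 0 fell.

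Cell cycle genes were higher in resistant cells. Of 50 measured, 33 rose and 0 fell, with 38 and 0 adjusted over the list alone (camera adjusted p = 8.96e-13, and adjusted p = 0.00532 with an estimated correlation), and the median change was 0.39. The cyclin gene CCNE2 rose by 2.17 ± 0.14, CDC20, an activator of the anaphase-promoting complex, by 1.39 ± 0.08 and CDC6, which licenses replication origins, by 1.35 ± 0.10. Heat shock genes were higher too, with 10 of 15 rising and 1 falling, the same adjusted over the list alone (camera adjusted p = 0.00103, and adjusted p = 0.115 with an estimated correlation). The co-chaperone genes DNAJA1 and DNAJB1 rose by 2.11 ± 0.06 and 1.78 ± 0.11 and HSPH1 by 1.75 ± 0.08. The 1 member that fell was the small heat shock protein gene CRYAB, by 2.95 ± 0.24.

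Interferon-stimulated genes were lower in resistant cells, in which the level of IFNB1 was lower as well. Of 41 measured, 25 fell and 1 rose, with 27 and 1 adjusted over the list alone (camera adjusted p = 8.07e-08, and adjusted p = 0.00870 with an estimated correlation), and the median change was -0.52. IFI27 fell by 3.52 ± 0.54, HERC5, a ligase for the ubiquitin-like protein ISG15, by 1.66 ± 0.06, IFI6 by 1.65 ± 0.08 and IFIH1, a sensor of double-stranded RNA, by 1.39 ± 0.14. In the list of antigen presentation by MHC class I, 7 of 15 fell and 4 rose, with 8 and 4 adjusted over the list alone, and HLA-C and HLA-B fell by 0.78 ± 0.07 and 0.72 ± 0.06, but the list was not called (camera adjusted p = 0.453). NF-kB targets were mixed, with 9 of 37 rising and 13 falling, or 10 and 15 adjusted over the list alone (camera adjusted p = 0.808). Among them the cytokine genes IL32, IL1B and CSF3 rose by 4.32 ± 0.21, 3.68 ± 0.10 and 3.44 ± 0.20, and the prostaglandin synthase gene PTGS2 by 2.66 ± 0.11. The sensitive levels of IL32 (1.52) and CSF3 (2.14) lay below that of the median probe set, so the size of their changes rests on noisy low signals. IL1B rose from 6.99 to 10.67. The median change of the list of NF-kB targets was -0.10 and its mean change 0.22, so the signs differ.

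**Figure D4:**
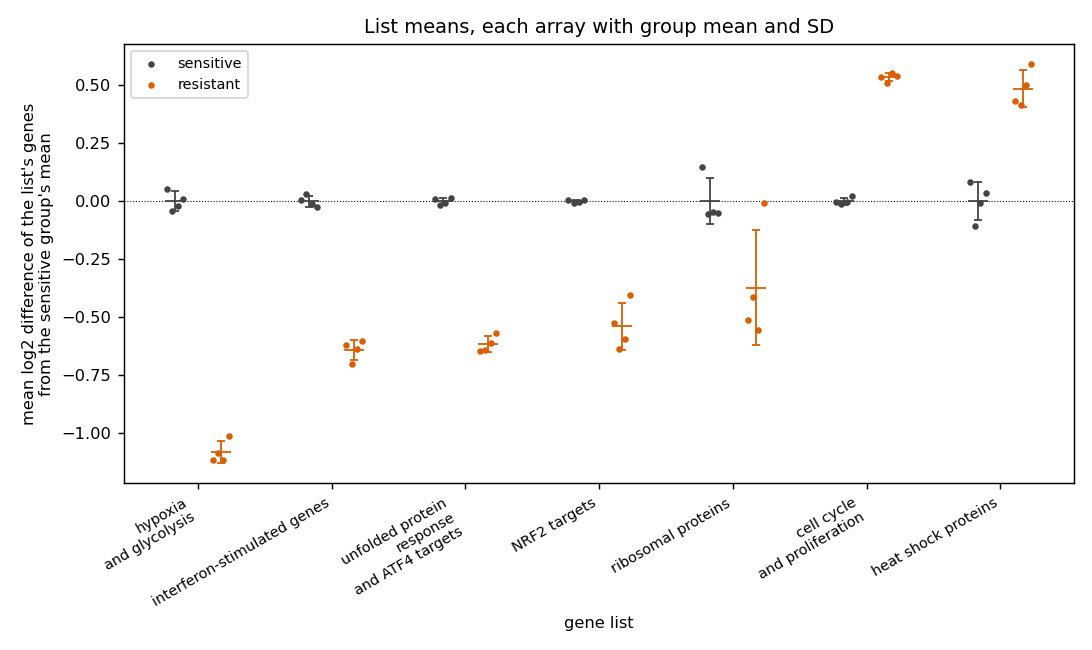
Mean log2 difference of each list's genes from the sensitive group's mean (y axis) for 7 gene lists (x axis), 1 point per array, with bars for the mean and SD of the 4 sensitive (grey) and 4 resistant (orange) arrays. The 4 resistant arrays lie between -1.11 and -1.01 for hypoxia and glycolysis, and for ribosomal proteins resistant array 4 lies at -0.01, apart from the other 3 resistant arrays.

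Genes of detoxification were lower, though these calls depended on the preset correlation. Of 28 NRF2 targets, 13 fell and 2 rose, with 19 and 2 adjusted over the list alone (camera adjusted p = 0.000107, and adjusted p = 0.115 with an estimated correlation). Besides AKR1B10, the transporter gene ABCC3 fell by 1.97 ± 0.19 and the epoxide hydrolase gene EPHX1 by 1.47 ± 0.11. Of 20 drug transporters and aldehyde dehydrogenases, 11 fell and 1 rose, or 11 and 4 adjusted over the list alone (camera adjusted p = 0.0173, and adjusted p = 0.115 with an estimated correlation). ABCG2, an efflux pump, fell by 1.16 ± 0.12, and the 1 that rose was the major vault protein gene MVP, by 2.07 ± 0.11. ABCC3 counts both here and among the NRF2 targets, so these lists are not fully separate results. Of 22 targets of MAPK and ERK signalling, 14 fell and 5 rose, the same adjusted over the list alone (camera adjusted p = 0.0298, and adjusted p = 0.270 with an estimated correlation). The ERK phosphatase gene DUSP6 fell by 1.82 ± 0.15 and ETV4 by 1.51 ± 0.10, while the cyclin gene CCND1 rose by 1.72 ± 0.10. The largest change among members that passed was a rise, that of HMGA2 by 2.55 ± 0.19, from a low sensitive level of 4.50. This list was also not called with the replicate numbers as a block (adjusted p = 0.0601), with dim probe sets left out (adjusted p = 0.0774) or after median centring (adjusted p = 0.0582). Of 16 cancer-testis antigens, 5 rose and 0 fell, or 7 and 0 adjusted over the list alone, among them MAGEA1 by 1.09 ± 0.09 and PRAME by 0.74 ± 0.09 (camera adjusted p = 0.0271, and adjusted p = 0.124 with an estimated correlation).

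The list of ribosomal proteins was called lower with 3 of 20 members falling and 0 rising, and 0 of either adjusted over the list alone (camera adjusted p = 0.00141, and adjusted p = 0.657 with an estimated correlation). RPL3 and RPLP1 fell by 0.46 ± 0.13 and 0.51 ± 0.15, from log2 levels above 14, and neither passed after quantile normalization (-0.10 and -0.09, adjusted p = 0.306 and 0.404), nor did the list (adjusted p = 0.711). The list was also not called with the mean of all probe sets of a gene (adjusted p = 0.0610). RPL3 did not pass without any of 5 and RPLP1 without any of 7 of the 8 arrays, with adjusted p-values up to 0.0794 and 0.107. These are among the brightest probe sets. An upper percentile of the probe sets was lower on resistant arrays by -0.40, which did not pass (exact p = 0.114, adjusted p = 0.20). The highest signal lay between 26649 and 33357 on sensitive arrays, between 17817 and 19994 on resistant arrays 1 to 3, and at 29134 on resistant array 4. The hybridisation spike-ins, added in equal amount to every array, were lower on resistant arrays by -0.35 (exact two-sided permutation p = 0.0286, the smallest possible, and 0.10 after Benjamini-Hochberg adjustment over 7 measures). Resistant arrays 1 to 3 lay at 10.63, 10.93 and 10.70, but resistant array 4 at 11.12, next to sensitive array 3 at 11.13. The dimmer bioB spike-ins among the hybridisation spike-ins differed by -0.34 (exact p = 0.0571, adjusted p = 0.133) and the poly-A spike-ins by -0.02 (exact p = 0.943). The ACTB 3' minus 5' difference was 0.23 on sensitive and 0.11 on resistant arrays, -0.12 apart (exact p = 0.0286, adjusted p = 0.10). The GAPDH difference was -0.14 and -0.13 (exact p = 0.686), and the array medians differed by -0.07 (exact p = 0.143).

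None of the 7 lists of markers of other cell types was called. The camera adjusted p was 0.0865 for alveolar and airway epithelium, 0.571 for squamous or basal epithelium, 0.771 for neuroendocrine lung cells, 0.808 for fibroblasts, 0.910 for hepatocyte or gut epithelium, 0.975 for endothelium and 0.999 for leukocytes. The list of alveolar and airway epithelium nonetheless had means of -1.12 to -0.58 on resistant arrays, apart from -0.15 to 0.11 on sensitive arrays, with a median change of -0.63. Of the 71 markers measured, 4 rose and 6 fell, or 4 and 6 adjusted over each list alone. Those that rose were POSTN, CHGB (1.82 ± 0.35), PI3 (0.92 ± 0.17) and S100A2 (0.90 ± 0.16). Those that fell were LUM (-3.27 ± 0.54), HOPX (-2.55 ± 0.10), CHGA (-1.68 ± 0.21), PDGFRB (-1.12 ± 0.26), SCG2 (-0.75 ± 0.08) and SFTPB (-0.63 ± 0.19). On probe sets without a cross-hybridisation suffix LUM turned to 0.75 (adjusted p = 0.451), SFTPB to 0.25 (adjusted p = 0.663), and HOPX did not pass (-1.34, adjusted p = 0.275). SFTPB did not pass without any of 7 of the 8 arrays, with changes of -0.76 to -0.49 and adjusted p-values up to 0.115.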

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

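Of the tests below, that of the ribosomal protein signals was chosen after the result was seen. Splitting the 8 arrays into 4 and 4 in other ways did not give gene counts of the observed size. Of 35 splits, the real one included, 1 gave as many changed genes (5986, against at most 5 in another split), 1 as many genes changed at least 2-fold (1533, against at most 5) and 1 as many changed probe sets (10637, against at most 7). For gene lists, 1 of 35 splits gave as many (10, against at most 7). For these 4 counts the real split thus ranked highest of the 35, which speaks only against chance having formed the groups of arrays. Splits that mix the groups add the group difference to the spread, so their low gene counts follow largely from the mixing. Another split also gave 7 lists at the preset correlation, and the arrays of a group may be technical replicates.

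In 17 of 328 groups of 4 arrays (5.18%), 1 array lay far from the other 3, which chance gives in about 5% of groups. The measure is the gap to the nearest array as a share of the group's range. Resistant array 4 stood apart in its mean correlation with its group (0.943 against a mean of 0.952, share 0.915), in the mean of oxidative phosphorylation genes (0.07 against -0.06, share 0.8998) and in FOXO3 (0.896), MAGEA1 (0.914), CSF3 (0.871) and GALNT14 (0.877). Sensitive array 1 stood apart in its highest signal (33357 against 27007, share 0.882), in the mean of ribosomal protein genes (0.15 against -0.05, share 0.950) and in HERC5 (0.834) and GALNT2 (0.953). Sensitive array 2 stood apart in MMP1 (1.87 against 4.16, share 0.843) and in the mean of NF-kB targets (-0.12 against 0.04, share 0.930). Sensitive array 3 stood apart in FAS (0.892) and in the ACTB 3' minus 5' difference (0.226 against 0.231, share 0.908). Resistant array 2 stood apart in that difference (0.133 against 0.105, share 0.8295) and in ETV4 (0.910), and resistant array 3 in SERPINB11 (0.833).

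Ribosomal protein signals were lower in resistant cells, with a median change of -0.38 over the list. A lower signal ceiling on resistant arrays 1 to 3 is a candidate explanation, since 118 other genes with a mean log2 level over 13 were lower too, with a median change of -0.23 (89 lower, 29 fell and 7 rose). Resistant array 4 lay at 0.06 in the mean of these other genes and at -0.01 in that of the list, while resistant arrays 1 to 3 lay at -0.34, -0.27 and -0.36 and at -0.51, -0.41 and -0.55. The median change of the list was -0.043 after quantile normalization, which decides little because it makes the brightest values alike, and the spike-ins do not speak for a ceiling, since the dim bioB ones differed as much (-0.34) as all hybridisation spike-ins (-0.35). A lower level of ribosomal protein transcripts in resistant cells stays open beside it.

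Hypoxia and glycolysis genes were lower in resistant cells, with a median change of -1.02. A lower signal ceiling would spare dimmer genes, but the 7 members with a mean log2 level under 10 had a median change of -1.41, and 6 of them fell. With the GAPDH 3' minus 5' difference as a covariate the median change was -1.01. That difference hardly differed between the groups (0.015), so this decides nothing. The ACTB difference separates the groups, at 0.23 on sensitive and 0.11 on resistant arrays (exact p = 0.0286, adjusted p = 0.10). It was lower where the listed genes were lower, which argues against more degraded RNA on resistant arrays, as far as this 1 transcript shows. A 3' end bias in the other direction stays open. Less crowded or better aerated cultures at harvest could give the same pattern and cannot be told apart from the resistance itself, since the labels of 0 samples give culture density or medium age. A biological difference that came with resistance stays open as well, and was not tested.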

How the results depend on the processing

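The pseudocount of 16, the removal of sensitive array 1 with resistant array 4 and, for single named genes, the intensity trend, array weights, dim filter, GAPDH covariate, unequal-variance test and suffix filter were tests chosen after seeing the data. Leaving out each array in turn gave 4928 to 5776 changed genes, 1404 to 1509 changed at least 2-fold, 7885 to 10134 probe sets and 10 lists each time. The group difference was then -0.0074 to 0.046 for GAPDH 3' minus 5', negative only without resistant array 3, -0.13 to -0.11 for ACTB and -0.096 to -0.042 for the array median. Without sensitive array 1 and resistant array 4, 5536 genes passed, 4925 of them among the 5986. A pseudocount of 16 gave 6393 genes, 5932 of them among the 5986, and 1032 changed at least 2-fold, against 1533. Changes of at least 1.5-fold numbered 3462, against 1533 at 2-fold, because the threshold is looser, and limma's treat against a log2 change of 0.58 gave 1107. Lists called numbered 4 with an estimated correlation and 30 with fry, which does not compare a list with other genes. Replicate numbers do not pair the arrays: correlations of the deviations of same-numbered arrays were -0.06, 0.10, 0.04 and -0.07, the highest for its number in 2 of 4. With these numbers as a block, 4356 genes passed, 4193 of them among the 5986, and 5062 probe sets against 10637, with fewer residual degrees of freedom. With this block TNFRSF10A, TNFRSF10B and TNFRSF10D did not pass (adjusted p = 0.0505, 0.0649 and 0.0542), nor did BID, CASP10, CYCS, MLKL, HTRA2, RPL3, RPLP1 and SFTPB (0.0679 to 0.114), and TNFSF10 did (0.0459). With the unequal-variance test TNFRSF21, CHGB, PDGFRB, CASP10, CYCS, TNFRSF10D, SFTPB and RPLP1 did not pass (adjusted p = 0.0506 to 0.117). The lists of hypoxia and glycolysis, cell cycle, interferon-stimulated genes and unfolded protein response kept their call under all 19 alternatives run on them, MAPK and ERK targets under 15, ribosomal proteins under 16 and the other 4 called lists under 18. Of 114 named genes that passed and were put to these alternatives, 89 kept their call under every alternative run on them and 3 turned in direction. With the mean of all probe sets of a gene, CFLAR turned to 0.11, FAS to -0.088, MTOR to -0.52 and TNFRSF10C to -0.050. On probe sets without a suffix LUM turned to 0.75, SFTPB to 0.25 and FAS to -1.17. Both settings use other probe sets by construction, and the cause of the remaining reversals was not tested. TRAF7 turned to 0.014 after median centring, and TNFRSF10C to -0.053 with the GAPDH covariate and -0.019 with a pseudocount of 16. When leaving out each array MTOR ranged from -0.044 to 0.216, with a negative value without sensitive array 1 or resistant array 3 (-0.0066). TNFRSF10C ranged from -0.27 to 0.41, with negative values without sensitive array 3 or 4 (-0.11) or resistant array 2 or 3 (-0.071 and -0.076). Changes of genes whose level lies near or below that of the median probe set are limited by low signal over background.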

Other observations

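The split test of neighbouring genes and the wider windows along the chromosomes were tests chosen after the results were seen. Growth factor and adhesion genes changed strongly in single members without a called shift of their lists. Of 32 receptor tyrosine kinases and ligands, 7 rose and 8 fell, or 8 and 12 adjusted over the list alone (camera adjusted p = 0.432). The growth factor gene PDGFA and the receptor gene AXL changed by -2.23 ± 0.07 and -1.99 ± 0.10 (SE, n = 4 per group), and the EGF receptor ligand gene TGFA rose by 2.07 ± 0.17. Of 36 mesenchymal markers, 11 rose and 10 fell, or 11 and 12 adjusted over the list alone (camera adjusted p = 0.847). CDH2, the gene of N-cadherin, rose by 2.65 ± 0.40 and WNT5A fell by 2.71 ± 0.19. Of 27 epithelial markers, 2 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.432), among them the tight junction gene CLDN7 (-1.29 ± 0.08) and the keratin gene KRT19 (-1.24 ± 0.10). Of 31 integrins, laminins and matrix adhesion genes, 9 rose and 11 fell, the same adjusted over the list alone (camera adjusted p = 0.645). The collagen receptor gene ITGA2 rose by 2.76 ± 0.10, the collagen gene COL12A1 fell by 1.61 ± 0.10, and MMP1, given above, counts here too. Of 22 Wnt, Notch and Hippo targets, 5 rose and 5 fell, or 6 and 5 adjusted over the list alone (camera adjusted p = 0.992). NOTCH3 fell by 2.90 ± 0.13, while DKK1, given above, rose by 4.63 ± 0.08. Of 19 TGF-beta targets, 4 rose and 8 fell, the same adjusted over the list alone (camera adjusted p = 0.172), and ID3 rose by 1.59 ± 0.16 while BHLHE40 fell by 1.60 ± 0.06.

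Enzymes that modify receptors with O-glycans changed in single members. Of 14 measured, 3 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.353). GALNT14 fell by 0.85 ± 0.08 and GALNT2 rose by 0.69 ± 0.09, both of which start mucin-type O-glycans. Of 30 p53 targets, 5 rose and 9 fell, or 6 and 10 adjusted over the list alone (camera adjusted p = 0.300), and GDF15 fell by 2.25 ± 0.07 while SFN rose by 1.73 ± 0.10. Of 20 genes of cholesterol synthesis and uptake, 7 rose and 5 fell, or 7 and 6 adjusted over the list alone (camera adjusted p = 0.426), and HMGCS1 and IDI1 rose by 1.31 ± 0.12 and 1.22 ± 0.09. On probe sets without a cross-hybridisation suffix GDF15 (-0.52, adjusted p = 0.708) and IDI1 (0.11, adjusted p = 0.761) did not pass. Of 9 IAP proteins and antagonists, 0 rose and 1 fell, or 0 and 0 adjusted over the list alone (camera adjusted p = 0.910). The 1 gene was HTRA2, which fell by 0.33 ± 0.09 and did not pass without any of 7 of the 8 arrays, with changes of -0.38 to -0.28 when leaving out each array and adjusted p-values up to 0.0757. Of 27 autophagy and lysosome genes, 2 rose and 9 fell, or 2 and 10 adjusted over the list alone (camera adjusted p = 0.0762), and the list was called lower after quantile normalization (adjusted p = 0.0394) and with the mean of all probe sets of a gene (adjusted p = 0.00736). Of 13 histone genes, 3 rose and 4 fell, or 3 and 5 adjusted over the list alone (camera adjusted p = 0.716), and of 22 oxidative phosphorylation genes 2 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.992). Median change, mean change and camera direction did not all share a sign for NF-kB targets, mesenchymal markers, integrins, pro-apoptotic BCL2 members, Wnt, Notch and Hippo targets, oxidative phosphorylation and the lists of squamous, neuroendocrine, fibroblast and leukocyte markers, of which none was called.

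Over windows of 21 neighbouring genes, genes that were lower in resistant cells clustered along 1 chromosome. Among 11610 ordered genes, of which 23.9% fell, the largest absolute median change over 21 neighbours was 0.964. The 95th percentile of the largest value in 1000 shuffles was 0.666. All 21 windows above that level were lower, in the runs FZD7 to XRCC5 (28 of 36 genes fell), CATIP-AS1 to STK16 (14 of 21) and TMEM198 to DAW1 (16 of 24). The runs were picked by these low values. Windows of a gene and its 50 neighbours on either side joined these runs into 1 from MAP3K2 to LINC01881 that holds CASP8, with a median change of -0.46 over 355 genes. They also gave 3 shorter runs on other chromosomes, of which 2 were lower (-0.29 and -0.26) and 1 higher (0.29). The largest window median in the run TMEM198 to DAW1, -0.750876, equals the change of SCG2, which thus probably lies there. Whether other genes named above lie in these runs was not examined, so some of their falls may not be separate results. In these wider windows 1 of 35 splits, the real one, gave a largest value as high (0.608, against at most 0.353). This speaks only against chance having formed the groups of arrays and is no evidence that changes cluster along a chromosome. A changed copy number of chromosome segments in the resistant population is a candidate explanation, as a hypothesis, while shared regulation of neighbouring genes was not tested and DNA was not analysed here; the genes that bound the runs were named after their values were seen.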
